A study of Arabidopsis thaliana with 24 samples.

How the data were processed

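Messenger RNA was measured in roots of Arabidopsis thaliana seedlings of the Col-0 accession. Seedlings aged 3 days were moved to mock medium, to 0.8 nM brassinolide (BL, a brassinosteroid hormone), to 4 µM L-kynurenine (Kyn, an inhibitor of the tryptophan aminotransferase TAA1 and its relatives, and so of auxin synthesis) or to both (BL+Kyn). Roots were harvested after 12, 24 or 48 h, and per the labels they were cut a short way from the tip. Each of the 12 groups had 2 libraries, 24 in all, which the series calls biological replicates. Libraries were made from total RNA with CEL-Seq2, a method that reads the 3' end of transcripts and here tagged each RNA with a pool of 3 barcoded primers. The replicate numbers were not treated as pairs. Correlations of replicate deviations between groups ran from -0.188 to 0.592 with a median of 0.041, and 20 of 66 pairs of groups were over 0.1. For 19 of 24 libraries the best-correlated library of another group had the same number, so a fit with a replicate term was run beside.

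According to the submitters' processing notes, reads were handled with Trim Galore, cutadapt 1.10, FastQC 0.11.5, TopHat2 2.1.0, HTSeq 0.6.1 and DESeq2 1.18.1 against the TAIR10 build. Whether molecular barcodes were collapsed and which strand was counted are not stated there, so counts are called reads here, and the lower bounds given for groups without reads cover counting error only. The authors deposited a table of normalized counts per library (the signal used here, on a linear scale). They also deposited a table of each treatment against mock at each time, with a log2 fold change, a p-value and an adjusted p-value per gene. In the deposited normalized counts each library's values were multiples of a single unit, and dividing by it gave whole reads (within 0.1) for 99.45 to 100% of the values. In mega-reads (M), replicates 1 and 2 held 9.30 M and 9.47 M in mock at 12 h, 31.37 M and 9.66 M at 24 h and 21.37 M and 10.47 M at 48 h. In BL they held 22.34 M and 9.80 M, 21.90 M and 9.66 M, and 9.47 M and 6.32 M at these times, and in Kyn 24.53 M and 8.84 M, 12.28 M and 8.76 M, and 10.00 M and 7.37 M. In BL+Kyn they held 17.23 M and 9.53 M, 21.06 M and 8.71 M, and 11.10 M and 8.57 M. The mean depth was 15.27 M for mock (SD 9.17, n = 6), 13.25 for BL (SD 6.99, n = 6), 11.96 for Kyn (SD 6.37, n = 6) and 12.70 for BL+Kyn (SD 5.22, n = 6). Normalized totals lay between 11679031 and 12344333. The table held 40246 features, of which 13446 had no read in any library and 26800 had reads. Gene coordinates (TAIR10 chromosome, start and end) came from the deposited table, and symbols from a reference annotation.

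Values were analysed in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Normalized counts were used as deposited, with a pseudocount of 1 before log2 transformation and a minimum mean of 5 over the 24 libraries, which left 18948 genes. A limma-trend model with 12 group means had 12 residual degrees of freedom. Each contrast was adjusted by the Benjamini-Hochberg method over all genes tested, and a gene is said to be called, to rise or to fall where its adjusted p lay under 0.05. The time-averaged contrasts compared 6 libraries with 6 (BL, Kyn and BL+Kyn with mock, BL+Kyn with BL, and BL+Kyn with Kyn), and the interaction set BL+Kyn against the sum of both single effects. Each treatment was also compared with mock at each time, mock at 48 h with mock at 12 h, and a moderated F test asked whether each response changed with time. Log2 values in the text are fitted values, given with their standard error (SE) where the test of a gene is described. "In 6 of 6 libraries" counts the libraries of the first-named treatment that lay on the stated side of the other group's mean at the same time, or, for the interaction, of the sum of the single effects. Called genes passed a test on these same libraries, so such counts describe their spread and add no separate support.

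The tests, thresholds, gene lists and the rule for named genes were fixed before the data were examined. For each time-averaged contrast the rule named the 6 largest rises and the 6 largest falls among called genes with a mean of at least 20, a symbol and the same sign at all 3 times. It added up to 4 called members of each list by smallest p and 17 key genes of brassinosteroid, auxin, cytokinin and meristem biology, of which EXPA5 was not tested. For single times it took up to 3 genes in each direction, and for the tests of time the 3 smallest p values. Of the genes this rule picked, 2 are not reported here, while counts and list tests include them. The 27 lists held 475 members: BR biosynthesis, BR perception and signalling, BR-induced markers, Aux/IAA, other early auxin response, auxin biosynthesis and tryptophan pathway, auxin transport, camalexin, type-A response regulators, ethylene response, jasmonate and wounding, iron deficiency, heat shock, flavonoid biosynthesis, expansins and XTHs, cytosolic ribosomal proteins, G2/M cell cycle, S phase and replication, endocycle and CDK inhibitors, root meristem and stem cell niche, root hair, non-hair epidermis, endodermis, xylem, phloem, root cap, and photosynthesis as a marker of green tissue. Lists with at least 3 tested members, 26 of them, were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast. The same test with an estimated correlation was run beside it. So was fry, which tests whether the genes of a list move on balance in one direction, but its results are not given here. Camalexin had too few tested members and is described by its genes. Terms of the gene notes in the reference annotation with 10 to 500 members, 241 of them, were tested among calls with Fisher's exact test (two-sided), with all tested genes that carry a term as background.

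Alternatives planned in advance were pseudocounts of 0.5 and 4, no filter or a minimum mean of 20, TMM or upper-quartile factors, a replicate term, only the groups compared, each library left out in turn, an estimated correlation for lists, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. After the data were seen, fits without both 12 h libraries with raised green-tissue transcripts, and fits with only 12 and 24 h, were added. A library left alone in its group was assumed to vary like the other groups. The procedure was tested on simulated data with 200 changed genes: the averaged BL contrast recovered 91% of 2-fold and 100% of 4-fold changes with 14 false calls among 205. At a single time 48% of 2-fold and 91% of 4-fold changes were recovered, with 10 false calls among 149. In simulated lists, 10 of 10 raised lists were found and 0 of 190 unchanged ones were called. Simulated genes varied independently of each other, so this cannot show how often lists of correlated genes are called falsely.

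A group without a read in either library was given a floor of 3 reads over the group, and a fold against it is a lower bound. This applied to AIL5 in mock at 12 h, GH3.3 in Kyn at 48 h and CYP94D1 in BL+Kyn at 12 h. TT10, OFP11, RHS6, FEZ, CAF1a and CYP94D1 had other groups with 1 to 3 reads. Fitted averages of these genes depend on the pseudocount and are no bounds. With the 3 groups at their floor, 2 list medians moved, both in the interaction: other early auxin response from 0.215 to 0.192 and meristem from -0.479 to -0.45.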

Results

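The series asked how brassinosteroid and auxin levels act together on root transcripts, with roots of Col-0 seedlings on mock medium, BL, Kyn or BL+Kyn. BL alone and Kyn alone each moved a limited set of genes, and BL+Kyn moved many more. Averaged over 12, 24 and 48 h, limma called 357 of 18948 tested genes in BL against mock (176 higher, 181 lower), 929 in Kyn (338 higher, 591 lower) and 6887 in BL+Kyn (3546 higher, 3341 lower).

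**Figure D1:**
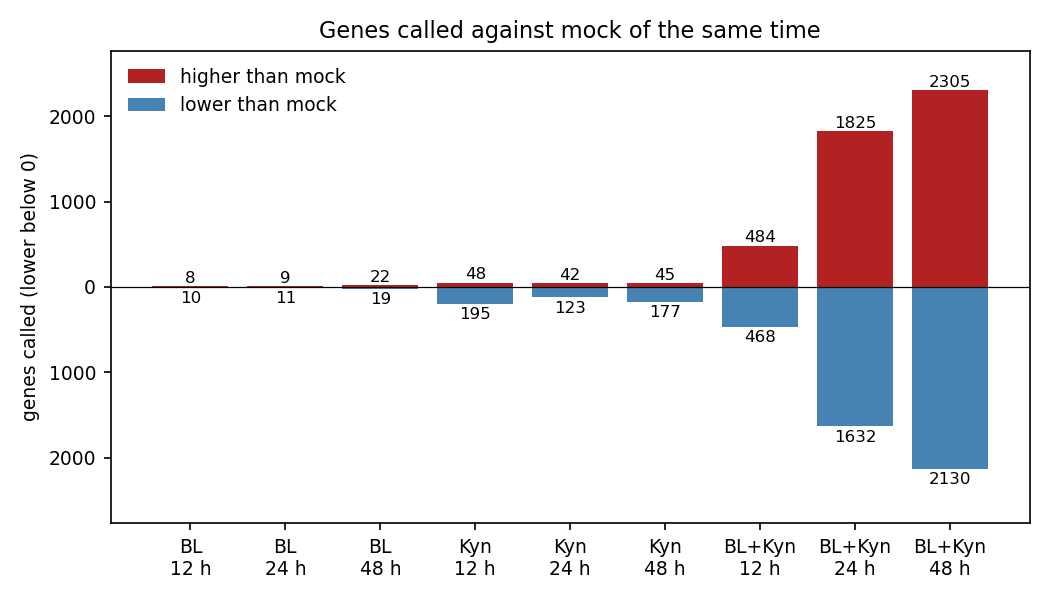
Number of genes called by limma (adjusted p under 0.05) against mock of the same time, for each treatment and time, with genes higher than mock above 0 and genes lower than mock below 0. BL+Kyn had 952 called genes at 12 h and 4435 at 48 h (1654 and 626 when only the groups compared were fitted), while BL stayed between 18 and 41 and Kyn between 165 and 243.

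BL lowered transcripts of brassinosteroid synthesis, and 357 genes in all were called. DWF4, the C-22 hydroxylase of brassinosteroid synthesis (chromosome 3, 18814140 to 18817244), fell by 1.09 on the log2 scale (SE 0.17, adjusted p = 0.00129). BR6OX2 and CPD, cytochrome P450 enzymes of the same pathway, had log2 changes of -0.74 and -0.50. MIOX4, a myo-inositol oxygenase that feeds the synthesis of wall sugars (chromosome 4, 13297698 to 13300387), rose by 2.39 (SE 0.31, adjusted p = 0.000253). ATGSTF13, a glutathione transferase (chromosome 3, 23217425 to 23218246), fell by 2.98 (SE 0.39, adjusted p = 0.000253). Each of these 5 genes moved in its direction in 6 of 6 BL libraries.

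Among other genes with large rises were the pectin-related sks9 (log2 1.48), the asparagine synthetase ASN1 (1.46), the aminotransferase AGT (1.40), the phospholipase NPC4 (1.52) and the acyl-CoA synthetase LACS1 (1.25). AGT, a gene of photorespiration, had a normalized count of 454.64 in the green-tissue library BL 12 h replicate 2 against 149.45 in its sister. AIL5, an AP2-type factor of the PLETHORA family also known as PLT5, rose by a fitted 2.05. It had no read in mock at 12 h and was at least 3.34-fold higher in BL at 12 h. Falls included the laccase TT10 (-2.39), scpl16 (-1.69), JAL22 (-1.51), AIR1 (-1.39), GRI (-1.35), the PLETHORA gene AIL6 (-1.09), the cytokinin response regulator ARR3 (-0.97) and the jasmonate synthesis gene AOS (-0.54). The auxin synthesis genes YUC3 (0.66) and YUC8 (0.40), the wall genes XTR6 (0.72) and XTH4 (0.30), the iron regulator FRU, also known as FIT (0.60), the non-hair regulator MYB66, also known as WEREWOLF (0.51), and IAA33 (1.24) rose. EXPA11 (-0.65), HAT2 (-0.30) and the ribosomal protein gene AT4G18100 (-0.29) fell. Of the 29 named calls, 27 showed their direction in 6 of 6 BL libraries, MYB66 in 5 and AT4G18100 in 4. Key genes that were not called include PLT1 (0.05), PLT2 (-0.34), WOX5 (0.64), CYCB1;1 (-0.27), IAA19 (0.18), GH3.3 (0.94) and RR5, also known as ARR5 (0.02).

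As a group, the BR biosynthesis list fell: 0 of 10 members rose and 3 fell over all genes (4 adjusted over the list alone), its median was -0.15 and lay below mock in 6 of 6 libraries (camera adjusted p = 0.000404). This call held with an estimated correlation (adjusted p = 0.0246). Cytosolic ribosomal protein genes, 171 tested, had a median of -0.07 with 1 called member and none adjusted over the list alone (camera adjusted p = 2.35e-05). That call gave an adjusted p = 0.875 with an estimated correlation and 0.115 with the preset one without BL 12 h replicate 1. The photosynthesis list had a median of 0.65 over time and 1.99 at 12 h, with no call (camera adjusted p = 0.0858). BL 12 h replicate 2 stood apart in it, at 4.15 above the mock mean on the log2 scale against 0.50 in the sister library. The other 23 lists were not called in BL. Signs of median, mean and test differed for BR perception, S phase, auxin biosynthesis, early auxin response, endocycle, iron deficiency, root cap and meristem lists. The count of 357 was 217 without mock 12 h replicate 2, 210 without mock 24 h replicate 2, 217 without mock 48 h replicate 2 and 215 without BL 24 h replicate 2. The calls of 18 of the 29 genes ended without at least 1 library, namely YUC3, YUC8, EXPA11, GRI, XTH4, XTR6, AGT, FRU, NPC4, ASN1, AT4G18100, CPD, MYB66, AOS, HAT2, TT10, AIL5 and IAA33, with adjusted p values of up to 0.167 (NPC4 without BL 24 h replicate 2). Without both green-tissue libraries 13 of the 29 calls ended, those of YUC3, YUC8, EXPA11, GRI, XTH4, AGT, FRU, NPC4, ASN1, AT4G18100, MYB66, HAT2 and IAA33 (up to 0.132, IAA33). With only 12 and 24 h 11 ended, those of YUC3, YUC8, XTH4, XTR6, LACS1, NPC4, AIR1, AT4G18100, HAT2, TT10 and IAA33.

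Kyn lowered auxin response genes and root hair genes, and raised a few genes very strongly. IAA19, an early auxin response gene (chromosome 3, 5264024 to 5265678), fell by 2.13 on the log2 scale (SE 0.18, adjusted p = 2.15e-07). PRP3, a wall protein of root hairs (chromosome 3, 23182722 to 23183994), fell by 2.19 (SE 0.18, adjusted p = 1.88e-07). CYP78A5, a cytochrome P450 also known as KLUH (chromosome 1, 4702725 to 4704657), rose by 5.21 (SE 0.21, adjusted p = 2.43e-11). TAA1, the enzyme that Kyn inhibits, fell by 0.82 (SE 0.15, adjusted p = 0.00206), and YUC8, which acts after it, rose by 1.38 (SE 0.10, adjusted p = 3.96e-08). All 5 moved in 6 of 6 Kyn libraries.

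Of 24 tested Aux/IAA genes, which are early auxin targets and repressors, 10 fell and 0 rose (14 adjusted over the list alone), with IAA31 at -2.46, IAA1 at -1.70 and IAA11 at -1.24. The list median was -0.48, and camera gave an adjusted p of 1.52e-14 (0.000366 with an estimated correlation). Among 9 other early auxin genes 4 fell (6 adjusted over the list alone; median -0.83, camera adjusted p = 2.44e-08, 0.00154 with an estimated correlation). These were GH3.3 (fitted -2.12), WES1, also known as GH3.5 (-2.06), GH3.1 (-1.75) and HAT2 (-0.58). GH3 enzymes join auxin to amino acids. GH3.3 had no read in Kyn at 48 h, at least 9.14-fold lower than in mock at 48 h. With only 12 and 24 h it was not called (adjusted p = 0.258). Of 10 root hair genes 7 fell (8 fell and 1 rose adjusted over the list alone), among them PRP1 (-2.68), COW1 (-1.69) and EXPA18 (-1.66). Their median was -1.30 (camera adjusted p = 2.18e-14, 0.0474 with an estimated correlation). Type-A response regulators, which cytokinin induces, had 2 of 8 lower (6 adjusted over the list alone), ARR4 (-0.51) and RR5 (-0.48). Their median was -0.39 (camera adjusted p = 3.54e-06, 0.0428 with an estimated correlation). Of 9 xylem genes 4 fell (7 adjusted over the list alone): the secondary wall cellulose synthases IRX1 (-0.73), IRX3 (-0.62) and CESA4 (-0.59) and the protease XCP2 (-0.35). The xylem median was -0.51 (camera adjusted p = 1.3e-06, 0.0787 with an estimated correlation). The medians of these 5 lists lay below mock in 6 of 6 Kyn libraries.

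Further large falls in Kyn were CYP94D1 (fitted -3.69), the arabinogalactan protein FLA6 (-3.65), ESE2 (-3.59), XTH26, a xyloglucan enzyme of root hairs (-3.59), OFP11 (fitted -3.41) and G3Pp2 (-3.06). Further rises were PRP4 (3.86), CYP706A2 (3.25), CYP706A1 (2.53), the peroxidase PA2 (2.57), LTP5 (2.40), XTR6 (1.47), XTH24 (0.58) and the brassinosteroid synthesis gene CYP90D1 (2.26-fold). The ethylene receptor genes ETR2 (0.76) and ERS2 (0.59) and FRU (0.72) rose, and PIN3, an auxin efflux carrier (-0.37), LGO, a CDK inhibitor (-0.58), XTH19 (-0.66), EXPA1 (-0.58), CYP79B3 (-0.60), ACS2 (-0.92), RGF2 (-0.98), VSP1 (-1.03) and the camalexin gene CYP71A12 (-2.10) fell. Of 47 named calls, 43 showed their direction in 6 of 6 libraries and 4 in 5. The photosynthesis list had a median of 0.29 over time and 1.31 at 12 h, and lay below mock in 5 of 6 libraries (camera adjusted p = 0.614). Kyn 12 h replicate 2 was at 3.77 above the mock mean and its sister at -0.57. Kyn 12 h replicate 2 and BL 12 h replicate 2 were singled out because green-tissue transcripts were high in them. Without both, the list median in Kyn was -0.47, while single mock libraries lay between -0.558 and 0.453 against the mock mean. Kyn at 12 h then rested on 1 library, so no fall is read from this. The other 20 lists were not called, with signs of median, mean and test that differed for S phase and flavonoid biosynthesis, and iron deficiency, flavonoid or auxin biosynthesis genes gave adjusted p values of 0.711, 0.957 and 0.711. The calls of ACS2, ERS2, RGF2, XCP2, EXPA1, IRX3 and VSP1 ended without at least 1 library, with adjusted p values of up to 0.164 (ACS2 without mock 48 h replicate 1). With only 12 and 24 h those of RGF2, XCP2, EXPA1, CYP79B3, IRX3, VSP1 and CESA4 ended as well (up to 0.614, VSP1), and without both green-tissue libraries those of ACS2, RGF2 and XCP2 (up to 0.128, XCP2).

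**Figure D2:**
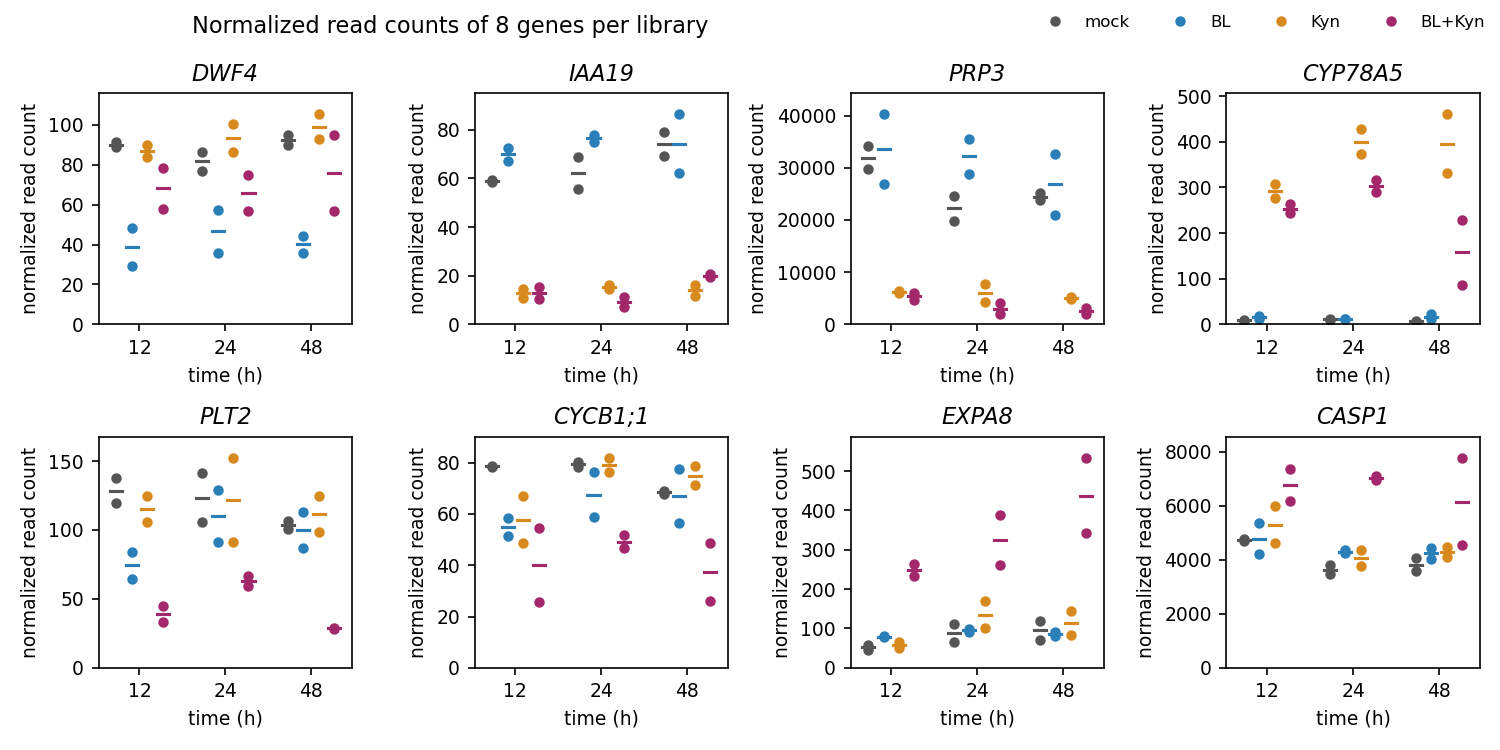
Normalized read count of 8 genes in each library (points, 2 per group) with the group mean (line), by time and treatment. DWF4 is lower in BL, IAA19 and PRP3 in Kyn and BL+Kyn, and PLT2 in BL+Kyn, while CYP78A5 is higher in Kyn and BL+Kyn and EXPA8 in BL+Kyn.

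With both compounds, 8 of 10 root hair, 158 of 171 ribosomal protein and 9 of 15 meristem genes were lower than in mock, and 7 of 8 endodermis and 5 of 8 ethylene response genes were higher. Camera called these 5 lists with the preset correlation and none with an estimated one (adjusted p = 0.291, 0.324, 0.305, 0.38 and 0.324 with an estimated correlation). CYP706A2, a cytochrome P450 gene (chromosome 4, 11934969 to 11936755), rose by 5.11 on the log2 scale (SE 0.41, adjusted p = 3.93e-08). PLT2, a transcription factor that maintains the root meristem (chromosome 1, 18977284 to 18980618), fell by 1.49 (SE 0.15, adjusted p = 7.43e-07), and PLT1 by 0.64 (SE 0.18, adjusted p = 0.00901). EXPA8, an expansin that loosens walls (chromosome 2, 16948863 to 16950557), rose 4.29-fold (log2 SE 0.19, adjusted p = 1.73e-07). CASP1, which builds the Casparian strip of the endodermis (chromosome 2, 15159591 to 15160750), rose by 0.70 (SE 0.11, adjusted p = 6.26e-05). Each of these 5 genes moved in 6 of 6 BL+Kyn libraries.

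Of 171 ribosomal protein genes, picked as cytosolic by their reference description though MRPL11 and NFD3 belong to mitochondrial ribosomes, 158 fell and 1, RPL18AA, rose (159 and 2 adjusted over the list alone), with a median of -0.46 that was below mock in 6 of 6 libraries. BL+Kyn 48 h replicate 1 stood apart, with a list median of -0.86 against -0.42 to -0.35 in the other 5. Camera gave an adjusted p of 4.13e-35, and 0.324 with an estimated correlation. Of 10 root hair genes 8 fell (9 adjusted over the list alone), with PRP1 at -3.54, PRP3 at -2.94 and EXPA18 at -2.66. Their median was -2.31 (camera adjusted p = 1.06e-10, adjusted p = 0.291 with an estimated correlation). In the endodermis list 7 of 8 rose (7 adjusted over the list alone), among them the regulator MYB36 (0.81) and ESB1 (0.62). The endodermis median was 0.66 (camera adjusted p = 0.000192, adjusted p = 0.38 with an estimated correlation), and BL+Kyn 48 h replicate 2 lay at 0.12 against 0.66 to 0.93 in the other 5 libraries. In the meristem list 9 of 15 fell and 2 rose (9 and 2 adjusted over the list alone), with the peptide gene RGF2 at -2.74, RGF3 at -1.24 and MGP at -0.88. Its median was -0.64 (camera adjusted p = 0.0133, adjusted p = 0.305 with an estimated correlation), with the same library at -0.22 against -0.89 to -0.53. Of 24 Aux/IAA genes 14 fell and 4 rose (15 and 5 adjusted over the list alone), with IAA31 at -3.39, IAA1 at -2.23 and IAA19 at -2.21 against IAA28 at 0.80. The Aux/IAA median was -0.34 (camera adjusted p = 0.0133, adjusted p = 0.291 with an estimated correlation).

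S phase genes had 4 of 16 lower (3 adjusted over the list alone): PCNA1 (-0.43), TSO2 (-0.39), PCNA2 (-0.36) and CDT1A (-0.32). Their median was -0.32 (camera adjusted p = 0.0133, adjusted p = 0.421 with an estimated correlation). G2/M genes had 7 of 21 lower (7 adjusted over the list alone), led by the mitotic cyclin CYCB1;1 (-0.89), CDKB1;2 (-0.76) and the cytokinesis gene SYP111, also known as KNOLLE (-0.36). The G2/M median was -0.22 (camera adjusted p = 0.0227, adjusted p = 0.47 with an estimated correlation), with BL+Kyn 48 h replicate 2 at 0.08 against -0.55 to -0.11 in the other 5. This G2/M call ended without mock 24 h replicate 1 (0.0642), mock 48 h replicate 1 (0.0537), BL+Kyn 12 h replicate 2 (0.063) or BL+Kyn 48 h replicate 1 (0.067), and with DESeq2 (0.0577). In the ethylene list 5 of 8 rose (5 adjusted over the list alone), with the receptor gene ETR2 at 0.95, ERS2 at 0.58 and EBF2 at 0.43. The ethylene median was 0.50 (camera adjusted p = 0.03, adjusted p = 0.324 with an estimated correlation, 0.0744 with no filter), and BL+Kyn 48 h replicate 2 lay at -0.11 against 0.39 to 0.60 in the other 5.

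Other lists had called members without a call of the list. Expansins and XTHs had 10 higher and 4 lower of 21 (camera adjusted p = 0.112), with XTR6 at 2.65, TCH4 at 2.34, XTH24 at 1.52 and EXPA15 at -1.02. Auxin biosynthesis had 5 higher and 1 lower of 13 (0.102), with YUC9 at 2.05, YUC8 at 1.99, YUC3 at 0.98 and TAA1 at -1.12. Auxin transport had 2 higher and 5 lower of 12 (0.0516), with LAX2 at -1.05, PIN3 at -0.63, LAX3 at -0.50 and ABCB19 at -0.43. BR biosynthesis had 2 higher and 4 lower of 10 (0.319), with CYP90D1 at 1.66, ROT3 at 0.45, BR6OX2 at -0.85 and CPD at -0.54, while DWF4 (-0.35) was not called. BR perception had 3 higher and 1 lower of 9 (0.748), among them the kinases BIN2 (0.49), BSK1 (0.34) and BAK1 (0.23) and the receptor BRL3 (-0.64). BR-induced markers had 2 higher, TCH4 and BAS1 (0.50), and 1 lower, IAA19, of 5 (0.98). Other early auxin genes had 1 higher and 4 lower of 9 (0.102), with WES1 at -2.36, HAT2 at -1.03, DFL1 at -1.15 and GH3.1 at -0.93. Phloem had 3 higher of 5 (0.143): SUC2 (0.76), APL (0.51) and AT5G57130 (0.51). Xylem had 2 higher of 9 (0.478), XCP1 (0.61) and XCP2 (0.44).

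Type-A response regulators had 2 higher and 3 lower of 8 (camera adjusted p = 0.319), with ARR3 at -1.31, ARR4 at -0.51, RR3 at 0.22 and ARR9 at 0.25. The endocycle list had 1 higher, ICK1 (1.13), and 3 lower of 8 (0.301), LGO (-1.13), ICK6 (-0.69) and FZR2 (-0.43). Heat shock had 2 higher of 6 (0.277), HSP70 (0.72) and HSP90.1 (0.65), iron deficiency 1 of 6 (0.941), FRU (1.43), flavonoid biosynthesis 1 of 7 (0.686), MYB12 (0.63), and non-hair epidermis 1 of 6 (0.941), MYB66 (0.41). Jasmonate had JAZ1 (0.55) higher and VSP1 (-1.08) lower of 6 (0.941), and root cap NAC070 (0.53) higher and FEZ (fitted -1.89) lower of 4 (0.941). No photosynthesis gene of 10 was called (0.753). PAD3, which makes camalexin, rose by 0.94. Signs of median, mean and test differed for BR-induced markers, iron deficiency and root cap. Large changes outside the lists included CYP94D1 (fitted -4.80), OFP11 (fitted -4.20), XTH26 (-3.99), XTH13 (-3.86), FLA6 (-3.84) and the extensin EXT6 (-3.70), and CYP706A1 (4.75), CYP78A5 (4.52), PA2 (4.50), MIOX4 (3.75) and the defence gene FMO1 (10.6-fold). CYP94D1 had no read in BL+Kyn at 12 h, at least 42.8-fold lower than in mock at 12 h. Of 95 named calls, 79 showed their direction in 6 of 6 libraries, 14 in 5, and HSP90.1 and AT5G57130 in 4. The calls of SUC2, GH3.1, CDT1A, RR3, MYB12, BRL3, PAD3, ARR9, NAC070, ICK6, HSP90.1 and DFL1 ended without at least 1 library, with adjusted p values of up to 0.167 (MYB12 without mock 48 h replicate 1), and that of CDT1A also without both green-tissue libraries. A fit of only 12 and 24 h ended 17 of the 95, those of FEZ, LAX3, ICK1, BAS1, CDT1A, RR3, HSP70, PAD3, ARR9, NAC070, FZR2, BAK1, ROT3, VSP1, PLE, HSP90.1 and AT5G57130.

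**Figure D3:**
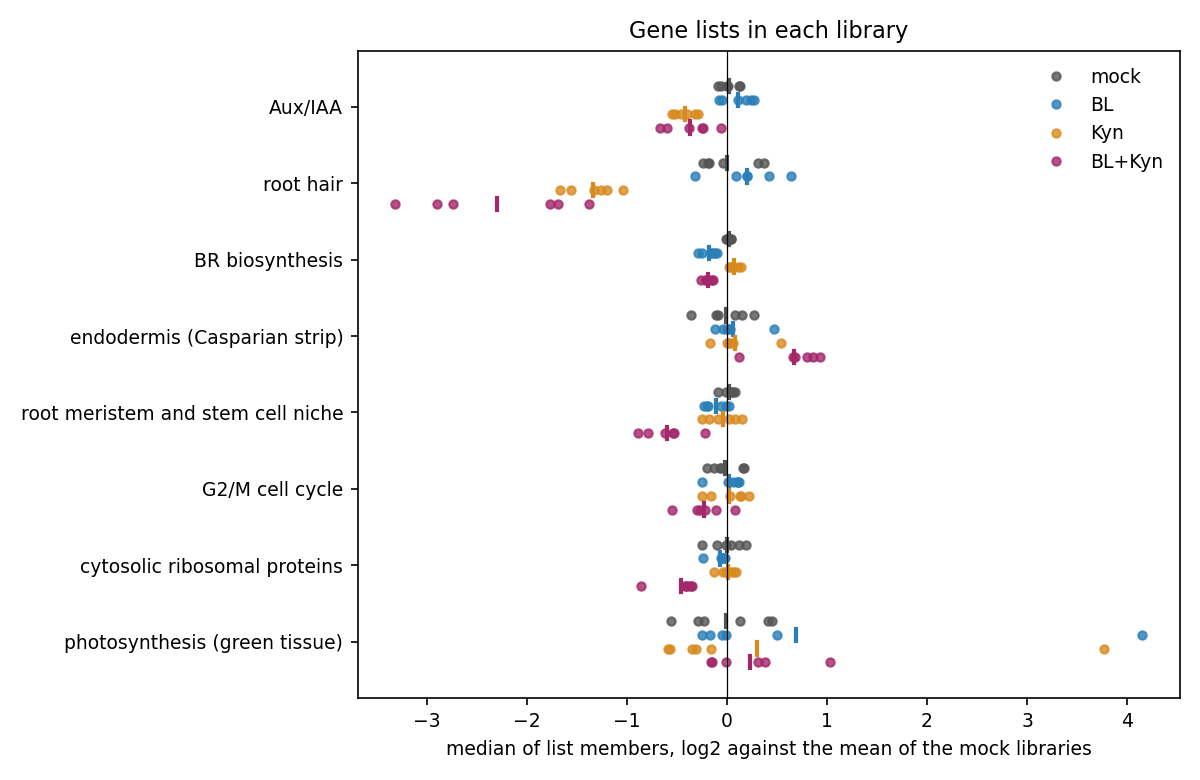
Median of the members of 8 gene lists in each library (points, 6 per treatment) on a log2 scale against the mean of the 6 mock libraries, with the treatment mean (line). Root hair medians lie below mock in Kyn and BL+Kyn, and 1 BL and 1 Kyn library of 12 h lie at 4.15 and 3.77 for the photosynthesis list.

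Adding Kyn to BL lowered 12 of 24 Aux/IAA, 9 of 10 root hair and 149 of 171 ribosomal protein genes and raised 7 of 8 endodermis genes. These 4 lists were called by camera with the preset correlation only (adjusted p = 0.0572, 0.106, 0.312 and 0.327 with an estimated correlation). BL+Kyn differed from BL in 5247 genes (2711 higher, 2536 lower). XTH26 (chromosome 4, 14244295 to 14245957) fell by 4.17 on the log2 scale (SE 0.25, adjusted p = 1.06e-09) and CYP706A2 rose by 4.40 (SE 0.41, adjusted p = 3.54e-07), both in 6 of 6 libraries. DWF4, which BL lowered, was 0.73 higher in BL+Kyn than in BL (SE 0.17, adjusted p = 0.00319, 6 of 6 libraries), whereas BR6OX2 (-0.11) and CPD (-0.04) were not called.

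Root hair genes fell in 9 of 10 cases (9 adjusted over the list alone; EXPA18 -2.98, LRX1 -2.64; camera adjusted p = 7.03e-14, adjusted p = 0.106 with an estimated correlation). Of 24 Aux/IAA genes 12 fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 5.23e-05, adjusted p = 0.0572 with an estimated correlation). Ribosomal protein genes fell in 149 of 171 cases and rose in 1 (153 and 1 adjusted over the list alone; median -0.39, camera adjusted p = 7.8e-35, adjusted p = 0.312 with an estimated correlation). Endodermis genes rose in 7 of 8 cases (7 adjusted over the list alone; ESB1 0.58; camera adjusted p = 5.23e-05, adjusted p = 0.327 with an estimated correlation). S phase fell in 4 of 16 (5 adjusted over the list alone; PCNA1 -0.47; 0.00266, adjusted p = 0.369 with an estimated correlation). G2/M fell in 4 of 21 (4 adjusted over the list alone; AUR2 -0.33; 0.00324, adjusted p = 0.393 with an estimated correlation). The meristem list fell in 5 and rose in 1 of 15 (6 and 1 adjusted over the list alone; PLT2 -1.15, PLT1 -0.68; 0.00757, adjusted p = 0.194 with an estimated correlation). Early auxin genes fell in 5 of 9 (5 adjusted over the list alone; WES1 -1.87; 0.0185, adjusted p = 0.194 with an estimated correlation). Ethylene genes rose in 4 of 8 (4 adjusted over the list alone; ETR2 0.68; 0.0263, adjusted p = 0.322 with an estimated correlation). The ethylene call ended without BL 24 h replicate 1 (0.0571), and the early auxin call without BL+Kyn 48 h replicate 2 (0.11) and with a minimum mean of 20 (0.0583).

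Beyond the lists, ESE2 (-4.13), XTH13 (-3.98), FLA6 (-3.94), EXT6 (-3.85) and CYP94D1 (fitted -4.76) fell, and CYP78A5 (3.87), CYP706A1 (12.1-fold), FMO1 (2.91), PA2 (2.88) and the sugar carrier SWEET11 (2.91) rose. The wall genes TCH4 (2.01), XTR6 (1.93), EXPA8 (1.89) and XTH24 (1.86), the auxin synthesis gene YUC8 (1.59), FRU (0.83), HSP70 (0.60), the indole glucosinolate gene CYP83B1 (0.54), JAZ1 (0.41) and BIN2 (0.41) rose as well. TAA1 (-1.30), LGO (-0.89), ICK6 (-0.81), EXPA15 (-0.83), LAX2 (-0.62) and PIN3 (-0.60) fell. Of 82 named calls 71 held in 6 of 6 libraries and 8 in 5, with IBH1 (0.40), CYP79B2 (0.28) and AOS (0.35) in 4. Photosynthesis genes had a median of -0.43 over time and -2.44 at 12 h, where BL 12 h replicate 2 was high. Signs of median, mean and test differed for BR biosynthesis, endocycle, flavonoid biosynthesis and iron deficiency, none of them called. The calls of 15 genes ended without at least 1 library, namely ERS2, XCP2, NAC015, ARR3, FAS1, PCNA2, ABCB1, RR3, IBH1, BAK1, CYCB1;1, CYP79B2, EBF2, AOS and PLE, with adjusted p values of up to 0.173 (NAC015 without BL+Kyn 48 h replicate 1). Leaving out both green-tissue libraries ended 10 calls, those of ERS2, XCP2, NAC015, FAS1, PCNA2, RR3, IBH1, BAK1, EBF2 and PLE (up to 0.113, NAC015). Of the 82 calls, 17 ended with only 12 and 24 h, those of MGP, XCP1, XCP2, ARR3, FAS1, AUR2, ABCB1, ABCB19, RR3, FZR2, BAK1, BSK1, CYCB1;1, CYP79B2, EBF2, AOS and PLE.

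Adding BL to Kyn lowered 8 of 15 meristem (1 rose), 159 of 171 ribosomal protein (1 rose) and 8 of 10 root hair genes and raised 6 of 9 xylem and 7 of 8 endodermis genes. Calls of these 5 lists by camera did not hold beyond the preset correlation (adjusted p = 0.254, 0.254, 0.335, 0.254 and 0.349 with an estimated correlation). BL+Kyn differed from Kyn in 5744 genes (2939 higher, 2805 lower), and in 3718 with only 12 and 24 h. RSL2, a bHLH regulator of root hairs, fell by 1.91 on the log2 scale (SE 0.17, adjusted p = 1.84e-06) and PLT2 by 1.45 (SE 0.15, adjusted p = 9.18e-06). The wall genes EXPA8 (1.77, SE 0.19, adjusted p = 1.08e-05) and EXPA1 (1.45, SE 0.16, adjusted p = 1.41e-05) rose, and all 4 moved in 6 of 6 libraries. IAA19 (-0.07), TAA1 (-0.30) and DWF4 (-0.43) were not called.

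Ribosomal protein genes fell in 159 of 171 cases and rose in 1 (161 and 1 adjusted over the list alone; median -0.47, camera adjusted p = 1.44e-46, adjusted p = 0.254 with an estimated correlation). Root hair genes fell in 8 of 10 (8 adjusted over the list alone; EXPA7 -1.25; 2.37e-05, adjusted p = 0.335 with an estimated correlation). The meristem list fell in 8 and rose in 1 of 15 (9 and 2 adjusted over the list alone; PLT1 -0.86, MGP -0.85; 0.00512, adjusted p = 0.254 with an estimated correlation). G2/M fell in 9 of 21 (10 adjusted over the list alone; CYCB1;1 -0.77, CYCA2;3 -0.52; 0.00271, adjusted p = 0.349 with an estimated correlation). S phase fell in 3 of 16 (3 adjusted over the list alone; PCNA1 -0.41; 0.003, adjusted p = 0.349 with an estimated correlation). Endodermis genes rose in 7 of 8 (7 adjusted over the list alone; MYB36 0.62; 0.000135, adjusted p = 0.349 with an estimated correlation). Xylem genes rose in 6 of 9 (7 adjusted over the list alone; XCP2 0.80, IRX1 0.68, CESA4 0.55; 0.000135, adjusted p = 0.254 with an estimated correlation). Phloem genes rose in 3 of 5 (5 adjusted over the list alone; SUC2 0.87, CVP2 0.58; 0.0409, adjusted p = 0.254 with an estimated correlation). The phloem call ended without Kyn 12 h replicate 1 (0.0579), Kyn 24 h replicate 2 (0.0595), Kyn 48 h replicate 1 (0.0666), BL+Kyn 12 h replicate 2 (0.0583), BL+Kyn 24 h replicate 1 (0.0505) or BL+Kyn 48 h replicate 1 (0.0614), with a minimum mean of 20 (0.055) and with only 12 and 24 h (0.0969).

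Other rises were CYP706A1 (2.22), ASN1 (2.11), CAF1a (fitted 2.11), the indole glucosinolate methyltransferase IGMT2 (4.29-fold), the pectin methylesterase ATPMEPCRB (2.04), the calmodulin-like TCH3 (1.97), TCH4 (1.76), BRU6, also known as GH3.2 (1.31), and BAS1, which inactivates brassinosteroids (0.89). ATGSTF13 (-2.89), RHS6 (fitted -2.33), RGF2 (-1.76), scpl16 (-1.66), RHS14 (-1.63), ARR3 (-1.01), BR6OX2 (-0.94), LAX2 (-0.87), CPD (-0.49) and EIR1, the auxin carrier PIN2 (-0.30), fell. GH3.3 (fitted 1.16) lay above Kyn in only 3 of 6 libraries and turned with only 12 and 24 h (-0.23, adjusted p = 0.756). Of 88 named calls 74 held in 6 of 6 libraries and 12 in 5, with GH3.1 (0.81) in 4. The photosynthesis median was -0.03 over time and -1.69 at 12 h. Without both green-tissue libraries the median was 0.68, with 1 library left in Kyn at 12 h, so no rise is read from this. Signs of median, mean and test differed for endocycle, heat shock and jasmonate lists, none of them called. The calls of 14 genes ended without at least 1 library, namely CVP2, FEZ, SMB, GH3.1, GH3.3, ICK1, HSFA2, PCNA2, CDKB1;2, HSP70, ACS6, ROT3, BRI1 and AT5G57130, with adjusted p values of up to 0.149 (AT5G57130 without BL+Kyn 12 h replicate 2). Leaving out both green-tissue libraries ended 8 calls, those of FEZ, SMB, GH3.3, ICK1, HSFA2, HSP70, ACS6 and BRI1 (up to 0.147, SMB). Of the 88 calls, 26 ended with only 12 and 24 h, among them those of CVP2, LRX1, CYCA2;3, FEZ, LAX3, SMB, GH3.1, CYP79B3, ICK1, PCNA2, IAA13, CDKB1;2, HSP70, DWF1, CAF1a, IRX1, FZR2, BAK1, ROT3, BRI1, CESA4, EIR1, AT5G57130 and ARR6.

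The combined effect differed from the sum of the single effects in 755 genes (315 higher, 440 lower). Among them, 6 of 10 root hair and 60 of 171 ribosomal protein genes lay below the sum and 2 of 9 xylem genes above it (camera lists called with the preset correlation, adjusted p = 0.239, 0.282 and 0.239 with an estimated correlation). Of the 755, 650 were also called in BL+Kyn against mock, a contrast that shares its libraries, and 595 were called in neither single treatment. EXPA7, an expansin of root hairs, lay 1.62 below the sum on the log2 scale, at -1.62 (SE 0.25, adjusted p = 0.00448). PLT2 was at -1.11 (SE 0.22, adjusted p = 0.0146), EXPA8 at 1.55 (SE 0.27, adjusted p = 0.00839) and XTH24 at 1.28 (SE 0.19, adjusted p = 0.00316). These 4 deviated in 6 of 6 BL+Kyn libraries.

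Among lists, 60 of 171 ribosomal protein genes lay below the sum and 0 above (143 and 1 adjusted over the list alone; median -0.38, camera adjusted p = 1.88e-45, adjusted p = 0.282 with an estimated correlation). Root hair genes lay below it in 6 of 10 (7 adjusted over the list alone; RSL2 -1.56, EXPA18 -1.33, LRX1 -1.11; 7.73e-09, adjusted p = 0.239 with an estimated correlation), and the meristem list in 2 of 15 (5 adjusted over the list alone; PLT1 -0.91; 0.00438, adjusted p = 0.239 with an estimated correlation). G2/M had 0 of 21 called and 0 adjusted over the list alone (median -0.31; 0.000526, adjusted p = 0.333 with an estimated correlation), and S phase 1 of 16, PCNA1 at -0.46 (1 adjusted over the list alone; 0.000929, adjusted p = 0.333 with an estimated correlation). Xylem lay above the sum in 2 of 9 (6 adjusted over the list alone; XCP2 0.64, IRX1 0.67; 3.09e-05, adjusted p = 0.239 with an estimated correlation). The endodermis list had 0 of 8 called and 7 higher adjusted over the list alone (median 0.49; 0.000108, adjusted p = 0.333 with an estimated correlation). Type-A response regulators had 1 of 8 higher, RR3 at 0.40 (3 adjusted over the list alone; 0.0167, adjusted p = 0.333 with an estimated correlation, and 0.0527 without Kyn 48 h replicate 1). The photosynthesis median was -0.62 over time and -3.68 at 12 h (camera adjusted p = 0.209). Without both green-tissue libraries the median was 0.56, with 1 library left in BL and in Kyn at 12 h, so no departure from the sum is read from this. Signs of median, mean and test differed for Aux/IAA, BR biosynthesis, BR perception, flavonoid biosynthesis and iron deficiency, none of them called.

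The interaction count was higher with DESeq2 and lower with no filter, as given further below. This count also depended on single libraries. It was 228 and 497 without mock 12 h replicates 1 and 2, 392 and 224 without mock 24 h replicates 1 and 2, and 356 and 248 without mock 48 h replicates 1 and 2. It was 235 without BL 12 h replicate 2, 234 and 355 without BL 24 h replicates 1 and 2, and 443 without BL 48 h replicate 2. It was 222 without Kyn 12 h replicate 2, 327 and 455 without Kyn 24 h replicates 1 and 2, and 393 and 302 without Kyn 48 h replicates 1 and 2. It was 151 without BL+Kyn 12 h replicate 2, 239 without BL+Kyn 24 h replicate 2 and 3086 without BL+Kyn 48 h replicate 2. Without both green-tissue libraries, which are in both single treatments, 91 genes were called. AXR3, PCNA1, CYP79B3, RR3, PLT1, IRX1, cwINV6, IAA28 and MRN1 lost their call without at least 1 library (up to 0.105, PLT1 without BL+Kyn 24 h replicate 2). EXPA7, EXPA8, XTH24 and RSL2 kept it without each single library. Of the 31 named calls, 16 ended without both green-tissue libraries, among them those of PLT2 (0.0694), PLT1 (0.157), AXR3, PCNA1, XCP2, RHS6, CYP79B3, RR3, IRX1, cwINV6, IAA28, MRN1 and the ribosomal protein genes RPSAb, AT2G20450 and AT3G16780 (up to 0.177, IRX1). With only 12 and 24 h 144 genes were called and 22 of the 31 named calls ended, among them those of PLT1, PLT2, EXPA1, EXPA7, EXPA8, EXPA15, EXPA18, RSL2, LRX1, RHS6, IQD20, AXR3, IAA28, PCNA1, XCP2, IRX1, AT2G20450, CYP79B3, CYP83B1, RR3 and MRN1.

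At single times fewer genes were called than over all times. In BL at 12 h 18 genes were called (8 higher, 10 lower), with the ethylene response factor gene ERF6 at -1.05 and MDHAR at 0.60. At 24 h 20 were called (9 higher, 11 lower), with AGP30 at -1.67, MIOX4 at 3.27 and MIOX2 at 1.33. At 48 h 41 were called (22 higher, 19 lower), with AIR1 at -2.16 and ATPMEPCRB at 1.95. When only the groups compared were fitted 0 genes were called at 12 h and 288 at 24 h, and DESeq2 called 54, 97 and 110 at the 3 times. Under TMM factors the share of higher genes at 24 h was 63.3% of 30 genes, against 45% of 20. Without mock 12 h replicate 1, mock 12 h replicate 2 or BL 12 h replicate 2 there were 0 calls at 12 h, and 7 without BL 12 h replicate 1. At 24 h there were 7 and 0 without mock replicates 1 and 2 and 4 and 1 without BL replicates 1 and 2. At 48 h there were 13 and 0 without mock replicates 1 and 2 and 6 without BL replicate 2. In Kyn 243 genes were called at 12 h (48 higher, 195 lower), 165 at 24 h (42 higher, 123 lower) and 222 at 48 h (45 higher, 177 lower), with 342 at 24 h in a fit of only the groups compared and 388 and 271 at 12 and 24 h in DESeq2. CYP78A5 was at 4.89, 5.10 and 5.63 at these times, FLA6 at -3.82 at 12 h and -3.57 at 24 h, and ESE2 at -3.75 at 48 h. Without mock replicates 1 and 2 and Kyn replicate 2 the 12 h count was 104, 112 and 121. Without mock replicates 1 and 2 and Kyn replicate 1 the 24 h count was 66, 19 and 32. At 48 h it was 77 and 99 without mock replicates 1 and 2 and 119 and 101 without Kyn replicates 1 and 2.

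In BL+Kyn 952 genes were called at 12 h (484 higher, 468 lower), 3457 at 24 h (1825 higher, 1632 lower) and 4435 at 48 h (2305 higher, 2130 lower). When only the groups compared were fitted these counts were 1654, 4497 and 626, so their order in time depended on the fit. The share of higher genes at 48 h was 52% and fell to 40.8% under upper-quartile factors. CYP706A2 was at 3.84, 5.73 and 5.75 at these times, XTH13 at -4.32 at 24 h, MIOX4 at 5.14 at 24 h, and the defence gene AZI1 at 6.06 and FLA6 at -4.00 at 48 h. Without mock replicates 1 and 2 and BL+Kyn replicates 1 and 2 the 12 h count was 444, 313, 532 and 324. The 24 h count was 1538 and 1463 without mock replicates 1 and 2 and 1056 without BL+Kyn replicate 2. At 48 h it was 2330 and 2694 without mock replicates 1 and 2 and 2222 without BL+Kyn replicate 1.

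The response to BL+Kyn changed with time in 219 genes (limma F test), with the defensin-like LCR69 at 2.28 and the arabinogalactan protein AGP13 at -1.46 for the 48 h effect minus the 12 h effect. For BL and for Kyn limma called 0 genes, with 788 and 595 of 18948 genes at an unadjusted p under 0.05. Both counts lay below the share of 0.05 that is due without any change with time. The other tools called 0 and 0 (edgeR) and 2 and 0 (DESeq2). For BL+Kyn, DESeq2 called more genes than limma and the fit of only the groups compared called fewer, as given further below. The BL+Kyn count was 70 and 49 without mock 12 h replicates 1 and 2, 37 and 115 without mock 48 h replicates 1 and 2, 110 and 51 without BL+Kyn 12 h replicates 1 and 2, and 453 and 1343 without BL+Kyn 48 h replicates 1 and 2. Without Kyn 12 h replicate 1 the Kyn test called 1 gene. Mock itself differed between 48 h and 12 h in 70 genes (29 higher, 41 lower), and in more with DESeq2 or with only the groups compared, as given further below. Among the 70 were the iron-related transporter OPT3 (-2.14), the ferric reductase FRO3 (-1.39) and ARL, a growth regulator (-1.73). That count was 0 and 12 without mock 12 h replicates 1 and 2, and 2 and 26 without mock 48 h replicates 1 and 2.

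Responses with and without the partner compound were compared across all tested genes, which are not independent replicates. The BL effect without Kyn and with Kyn had a Pearson r of 0.364 (Spearman rho 0.338; 0.339 from replicates 1 alone and 0.149 from replicates 2). The Kyn effect without BL and with BL had an r of 0.598 (rho 0.328; 0.588 and 0.343). The averaged main effects of both compounds had an r of 0.366 (rho 0.435, with 0.326 and 0.289 from replicates 1 and 2). Each main effect averages the effect without and with the partner, so any departure of BL+Kyn from the sum enters both. This r therefore does not show that BL alone and Kyn alone moved the same genes. Both green-tissue libraries are among replicates 2. Without BL 12 h replicate 2 the r of the BL effects was 0.4215, and without Kyn 12 h replicate 2 that of the Kyn effects was 0.6387. The r of the main effects was lower without either, at 0.3304 and 0.3348. Of 176 genes that BL raised, 142 were also higher in BL+Kyn than in Kyn (27.3 for independent lists), and of 181 that it lowered 122 were lower (26.8). Of 338 genes that Kyn raised, 281 were also higher in BL+Kyn than in BL (48.4 for independent lists), and of 591 that it lowered 427 were lower (79.1). Of the 6887 genes called in BL+Kyn against mock, 5907 were called in neither single treatment. A call in only 1 contrast is not itself a difference between contrasts. Over all tested genes the BL+Kyn effect had a Pearson r of 0.719 with the sum of the single effects (slope 0.7805). Both sides of that comparison share the mock libraries. The interaction test called 755 genes.

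The authors' deposited adjusted p-values called 127, 121 and 151 genes in BL at 12, 24 and 48 h, 471, 275 and 332 in Kyn, and 1192, 3729 and 4689 in BL+Kyn. Of the genes called here with limma, 18, 20 and 40 in BL, 235, 159 and 210 in Kyn, and 886, 3289 and 4142 in BL+Kyn were among these, each in the same direction. Deposited and fitted log2 values had a Pearson r across genes of 0.869 to 0.919.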

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

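Results listed here came from tests of whether one effect differed from another, which is why they are set apart. The interaction called 755 genes in which BL+Kyn differed from the sum of the BL and Kyn effects, and 219 genes responded to BL+Kyn differently over time. Interaction values on the log2 scale were -1.62 for EXPA7, -1.62 for CCP3, -1.33 for EXPA18, -0.74 for EXPA15, 1.27 for EXPA1, 1.55 for EXPA8 and 1.28 for XTH24 among expansins, wall genes and CCP3. Root hair genes were RSL2 at -1.56, RHS13 at -1.60, RHS14 at -1.70, RHS6 at -2.25 (fitted, low reads) and LRX1 at -1.11. Meristem and cell cycle genes were PLT2 at -1.11, PLT1 at -0.91 and PCNA1 at -0.46, and ribosomal protein genes RPSAb at -0.92, AT3G44590 at -0.68, AT3G16780 at -0.65 and AT2G20450 at -0.60. Hormone genes were AXR3 at 0.36, IAA28 at 0.42, RR3 at 0.40, ACS5 at 1.35, CYP79B3 at 0.71 and CYP83B1 at 0.68. Others were XCP2 at 0.64, IRX1 at 0.67, cwINV6 at 1.48, MRN1 at 1.70 and IQD20 at -1.66. For the BL+Kyn effect at 48 h minus that at 12 h, LCR69 was at 2.28, AGP13 at -1.46 and J11 at 3.09.

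For the interaction, the tests of green-tissue libraries and of 48 h were chosen only after the result was seen, as was the spread of the 48 h test, which replaced a spread over genes that would have excluded 48 h alone. Uneven counting noise did not account for it, since thinning each library to 6.32 M reads left a median ratio of 0.999 to the full log2 values. Thinning cannot change the expected level of a well-counted gene, so other effects of depth on the interaction were not tested. The 2 green-tissue libraries could have set it, yet without them the ratio was 0.927 (0.807 to 1.06 over 20 fits), although only 91 genes were then called. At 12 and 24 h the ratio was 0.827 (0.767 to 0.894 when 1 library was left out), above the 0.5 that 48 h alone would have allowed but not clear of the 0.8 set for excluding it. These ratios were taken over genes called with all libraries, which favours values near 1, so how far 48 h carried the interaction stays open.

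For the green-tissue transcripts in BL 12 h replicate 2 and Kyn 12 h replicate 2, the depth test was chosen only after the result was seen and the others before. Low depth did not account for them, as other libraries of at most their depth reached a photosynthesis median of 0.412. Greening of root cells alone was tested on leaf and shoot identity genes with a low mean in the other libraries. In the lower of both libraries these summed to 9.266 times the highest other library, which argues against greening alone. STM, 1 of these genes, was not raised (0 and 1.34). Identity genes with a higher mean were left out of the sum and moved little, among them KAN1 (108.77 and 101.72 against 104.81) and CER1 (72.11 and 84.32 against 56.02). RNA of shoot tissue in these libraries may account for the green-tissue transcripts, given the sum of the identity genes. Photosynthesis enzymes outside the list had a median of 3.361 on the log2 scale over the sister library in the lower of both libraries. Greening of root cells would raise these enzymes too, so they do not tell the 2 explanations apart. How shoot RNA came into cut roots stays open.

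For lower ribosomal protein transcripts in BL+Kyn, no test was chosen after the result was seen. Under TMM and upper-quartile factors the list medians were -0.481 or below. The median of all tested genes was -0.018 and -0.05 under these factors, against -0.001 as deposited, so they could hardly have undone the fall. The list fell relative to the other tested genes, and whether its absolute level fell was not tested. Short and abundant transcripts did not account for the fall, since matched genes had a median of -0.028. After thinning to equal depth the list median was -0.47. Thinning could hardly move transcripts this abundant (median normalized count 3927.1), so it does not settle an effect of depth. A smaller share of meristem cells might lower these transcripts, which was not tested, and with an estimated correlation the list gave an adjusted p of 0.324.

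Exchanging treatment labels within times gave 1 of 100 splits, the real one, with as many calls for BL (357, highest other 58), Kyn (929, 197), BL+Kyn (6887, 5010), BL+Kyn against BL (5247, 2970) and BL+Kyn against Kyn (5744, 3675). Chance alone was thus unlikely to give these counts, though 100 splits cannot give a share under 1 in 100. For the interaction 2 of 100 splits called as many or more genes (755, highest other 1350). These splits exchange all treatments, so single effects can enter the contrast. Why a split called many more genes was not tested.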

How the results depend on the processing

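With 2 libraries per group, counts at single times, of the interaction, of mock over time and of the BL+Kyn response by time moved most between settings, and the cause was not tested. The planned replicate term, tools, filters and scalings were fixed before the data were examined, while leaving out both green-tissue libraries and using only 12 and 24 h were added afterwards. A library left alone in its group was assumed to vary like the other groups.

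With no filter, 342 genes were called in the interaction, 33 in BL at 12 h, 107 in Kyn at 24 h and 1 in the Kyn response by time, and the correlation of main effects was 0.3061. With a minimum mean of 20, or among genes with a mean of 20 or more, that correlation was 0.4131. A replicate term gave 37 calls in BL at 24 h. An estimated correlation left 5 list calls of 40. DESeq2 called 1429 in the interaction, 54, 97 and 110 in BL at 12, 24 and 48 h, 388 and 271 in Kyn at 12 and 24 h, 201 in mock over time, 2 in the BL response by time and 551 in that of BL+Kyn. With only the groups compared, calls were 0 and 288 in BL at 12 and 24 h, 342 in Kyn at 24 h, 1654 and 626 in BL+Kyn at 12 and 48 h, 372 in mock over time and 125 in the BL+Kyn response by time. Results of named genes lost their call in 42 cases with no filter and in 33 with only the groups compared. With upper-quartile factors 14 lost and 2 gained a call, and with TMM factors 6 and 1. With edgeR 12 lost and 1 gained a call, with DESeq2 11 and 3, and with a replicate term 3 and 2.

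Without both green-tissue libraries, 91 genes were called in the interaction, 0 in BL at 12 h and 132 in Kyn at 12 h, and the correlation of main effects was 0.3315. The photosynthesis median then turned to -0.47 in Kyn, 0.677 in BL+Kyn against Kyn and 0.558 in the interaction. With only 12 and 24 h, 3718 genes were called in BL+Kyn against Kyn and 144 in the interaction, the correlation of main effects was 0.2781, and GH3.3 in BL+Kyn against Kyn turned to -0.227.

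Leaving out 1 library at a time gave, from lowest to highest, 210 to 368 calls in BL, 693 to 820 in Kyn, 5685 to 8027 in BL+Kyn, 4004 to 6604 against BL, 4418 to 7074 against Kyn and 151 to 3086 in the interaction. At 12, 24 and 48 h it gave 0 to 7, 0 to 7 and 0 to 44 in BL, 104 to 278, 19 to 112 and 77 to 119 in Kyn, and 313 to 532, 1056 to 2537 and 2222 to 5849 in BL+Kyn. Mock over time gave 0 to 26, responses by time 0 to 0 for BL, 0 to 1 for Kyn and 37 to 1343 for BL+Kyn, and list tests 39 to 50. Correlations ran from 0.2765 to 0.4215 for BL without and with Kyn, 0.5116 to 0.6387 for Kyn without and with BL and 0.3256 to 0.4281 for main effects.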

Other observations

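Terms of the reference gene notes, whose genes can also be list members, were tested among the calls (Fisher's exact test, two-sided, adjusted over 241 terms). This test counts genes as independent, though genes of a term can move together. Its p values therefore do not measure spread between libraries and can be far too small. In Kyn, lipid transport held 8 of 54 genes among the higher calls (1 for independent lists, adjusted p = 0.00187) and response to oxidative stress 11 of 128 (2.5, 0.00271). Plant-type cell wall organization held 9 of 21 genes among the lower calls of Kyn (0.7, 1.31e-06), and response to auxin stimulus 9 of 48 (1.5, 0.00142). Oxidation reduction held 14 of 426 genes among the higher calls of BL (4.5, 0.0368), 22 of Kyn (8.2, 0.0027) and 133 of BL+Kyn (80.7, 7.78e-08).

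In BL+Kyn the higher calls held 49 of 128 genes of response to oxidative stress (24.3 for independent lists, adjusted p = 1.55e-05 by Fisher's exact test), 27 of 62 of response to water deprivation (11.7, 0.000284), 22 of 54 of response to wounding (10.2, 0.00394), 21 of 50 of response to chitin (9.5, 0.00394) and 9 of 14 of trehalose biosynthesis (2.7, 0.00456). The lower calls held 263 of 362 translation genes (69.8, 2.15e-109), 83 of 100 of ribosome biogenesis (19.3, 3.34e-41), 17 of 30 of tRNA aminoacylation (5.8, 0.000293) and 9 of 11 of protein targeting to mitochondrion (2.1, 0.000551). Plant-type cell wall organization held 13 of 21 genes among the lower calls of BL+Kyn against mock (4.1, 0.000729), 12 against BL (3.1, 0.000334), 10 against Kyn (3.5, 0.0112) and 7 of the interaction (0.6, 9.78e-05). Nucleosome assembly held 26 of 48 genes lower than in BL (7.1, 1.72e-08).

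Green-tissue transcripts differed between sister libraries of 12 h. RBCS1A, the small subunit of Rubisco, had a normalized count of 53366.8 in BL replicate 2 against 2763.8 in replicate 1, and 64811.3 in Kyn replicate 2 against 771.9 in replicate 1. The leaf gene YAB1 was at 26.89 and 14.72 in these 2 libraries, against a mean of 0.03 elsewhere, and the shoot epidermis gene CER6 at 81.88 and 93.69 against 1.81.

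BL+Kyn 48 h replicate 1 lay at 78.4 on the first principal component and its sister library at 42.3, with heat shock list medians of 1.23 and 0.77 against the mock mean.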
